A study of Mus musculus with 36 samples.

How the data were processed

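The values of the authors were used as deposited, 36 arrays by 45101 probe sets. Per the submitters' processing notes they were computed with RMA, whose version is not given in the sources used here, and their values are on the log2 scale, which their range fits. Per the labels' protocols the mice were assigned to treatment at random, brain slices were kept in RNAlater, RNA of 2 tissue pieces was pooled for VTA and NAC arrays where its integrity number was above 7, and PFC RNA had integrity numbers of 7 to 10. Raw probe intensities, scan dates and the behaviour of the mice were not analysed here. No 2 arrays were identical, and every array was matched to 1 label.

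Of the 45101 probe sets 64 were controls, 34945 had 1 gene symbol, 932 had several and 9160 had none. Symbols were matched to current ones through the Entrez identifier for 34741, and 18193 genes were covered. In each comparison the probe sets whose mean over the arrays of its own fit lay at or above the 40th percentile were tested. That made 27022 in every comparison, but not the same ones, so the number of tested list members differs between comparisons. Probe sets without a single symbol were tested and counted but not named, 8 of those called in VTA, 3 in PFC and 24 across the regions.

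Each comparison was fitted with lmFit and eBayes of limma 3.58.1 in R 4.3.3, with p-values adjusted by the Benjamini and Hochberg method and a threshold of 0.05. Modafinil was compared with vehicle within VTA, NAC and PFC, each from its own arrays, and across the 3 regions with region as a factor over 36 arrays. The 3 differences of the modafinil change between regions were contrasts of 6 group means. NAC and VTA were compared in vehicle mice, in a fit of all 18 vehicle arrays, so the vehicle PFC arrays entered its filter and its estimate of the spread. A level contrast with PFC was not run, because the PFC values were on another scale. After quantile normalization of all arrays together the median of all genes moved by 0.217 and 0.23 in vehicle and modafinil VTA arrays, 0.17 and 0.174 in NAC and −0.249 and −0.244 in PFC. The median treatment change over all probe sets went from −0.0099 to −0.0042 in VTA, from −0.0086 to −0.0038 in NAC and from −0.00091 to 8.4e-05 in PFC. The changes within a region were therefore read from the deposited values.

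The 23 gene lists were written from general knowledge, and members were named before the data were examined. They held interferon gamma-induced and antigen presentation genes, immediate early genes, markers of midbrain dopamine, striatal, cortical and thalamic, hypothalamic and raphe neurons, monoamine, orexin and histamine receptors and transporters, glutamate receptors, GABA genes, neuropeptides, clock genes, glucocorticoid-responsive genes, heat shock genes, markers of oligodendrocytes, astrocytes, microglia, vessels, choroid plexus, meninges and red blood cells, ribosomal protein genes and oxidative phosphorylation genes. Each gene was read from the probe set with the highest mean over all arrays. Lists were tested with camera of limma, with a preset correlation of 0.01 between genes and again with an estimated correlation. Adjusted over the list alone means that the p-values of a list's members were corrected among themselves. The level of a list in an array was the mean of its members, compared between groups by exact permutation. Members also held by another list numbered 10 of 23 for neuropeptides, 6 of 22 for thalamic, hypothalamic and raphe markers, 4 of 23 for striatal markers, 2 of 19 for GABA genes, 1 of 19 for clock genes, 1 of 24 for cortical markers and 0 for the others. The median, mean and test of a list differed in sign for 8 lists in VTA, 6 in NAC, 7 in PFC and 7 across the regions, and of these the GABA list in VTA and the monoamine list across the regions were called.

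The genes named were fixed by rule before the data were examined. In each treatment comparison they were up to 10 genes past the threshold per direction with the largest changes, the 6 smallest p-values per direction where fewer than 20 genes passed, up to 2 members per direction of each list by smallest p, and a fixed set of dopamine, immediate early and interferon genes. In the interactions they were the 5 smallest p-values, and between regions the 8 largest differences per direction and up to 4 members of each marker list. Not every gene so chosen is printed.

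On simulated arrays with the same groups and known changes in 200 of 27022 probe sets, a change of 0.5 was found in 70.2 percent of changed probe sets in VTA, 55 in NAC, 88 in PFC and 97 across the regions, and a change of 1 in 97.8, 91.5, 99 and 100 percent. Of all calls, 3.14, 3.42, 5.1 and 3.66 percent were unchanged probe sets. In the interactions a change of 0.5 was found in 53.5, 53.1 and 58.2 percent, and a change of 1 in 93.9, 93.8 and 95 percent. Between regions these were 77.8 and 95.7 percent, with 16.1 percent of calls unchanged there. A list shifted by 0.5 was called in each region, and of the unshifted lists 0, 0 and 1 were called. The simulated probe sets varied independently of each other, while the correlation estimated within the interferon list in VTA was 0.422. The simulation therefore does not show how often the preset test calls lists of correlated genes by chance.

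Alternatives chosen before the data were examined were no filter, a filter at the 60th percentile, quantile normalization again, subtraction of array medians, eBayes with a trend and robust estimation, arrayWeights, 1 probe set per gene, a threshold of 0.1, replicate numbers as a block, all 36 arrays in 1 fit, a random block for animals, each array left out in turn, the estimated correlation, and the mean of a gene's probe sets in the lists. The removal of 5 doubted arrays (vehicle VTA array 4 for choroid plexus markers, vehicle NAC array 1 for dim bright probe sets, modafinil PFC array 3 for striatal markers, and vehicle PFC arrays 3 and 4 for meningeal markers) and the dopamine marker level as a covariate were added after the data were seen. The group labels were also redrawn 100 times.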

Results

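Messenger RNA of 3 brain regions was measured in male C57B1/6J mice on 36 Affymetrix mouse genome arrays. These are single-colour arrays on which a probe set reads part of a transcript, and some probe sets read several related transcripts. Modafinil is a wakefulness-promoting drug that blocks the dopamine transporter. The mice had gone through conditioned place preference, a test in which a drug is paired with a compartment and the time the animal later spends there is recorded. Treated mice received modafinil at 65 mg per kg on the drug days of conditioning (days 3 to 10), and control mice received saline, called vehicle here. Brains were taken after the test on day 11, 24 h after the last dose. Punches 1 mm wide were taken from slices 100 µm thick through the ventral tegmental area (VTA), which holds the dopamine neurons of the reward pathway. The other regions were the nucleus accumbens (NAC), their main striatal target, and the prefrontal cortex (PFC). There were 5 vehicle and 5 modafinil arrays of VTA, 5 and 5 of NAC, and 8 and 8 of PFC. The labels do not state that each array within a group came from a separate mouse, so the p-values measure only the spread between these samples. Values are on the log2 scale. The mean correlation of an array with the others of its group was 0.989 to 0.994 in VTA, 0.987 to 0.995 in NAC and 0.99 to 0.995 in PFC. The number of arrays limits the precision of every value given here.

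In vehicle mice the NAC and VTA arrays carried the marker genes of the 2 regions named in the labels. The dopamine transporter gene Slc6a3 was lower in NAC by 5.25 (log2 difference, SE 0.32, n = 5 each). Ret, a growth factor receptor gene of dopamine neurons, stood at 10.61 ± 0.67 in VTA and 5.87 ± 0.096 in NAC (mean ± SD), a difference of −4.74 (SE 0.25). Of 12 tested midbrain dopamine neuron markers, 11 were lower in NAC. Of 21 tested markers of striatal projection neurons, 20 were higher in NAC, among them Gpr6 by 4.95 (SE 0.23), Arpp21 by 4.10 (SE 0.21) and the transcription factor gene Bcl11b by 3.35 (SE 0.16). The counts were the same adjusted over the list alone. Among probe sets kept by the filter and past the test, the largest differences upward in NAC were those of Crym (6.81), Rin1 (5.75), Tbr1 (5.50), Egr2 (5.47), Ccn3 (5.30), Ankrd63 (5.30), Ankrd33b (5.07) and Abi3bp (5.04). Those downward after Slc6a3 and Ret were Slc17a6 (−4.08), Adcyap1 (−3.74), Igsf1 (−3.67), Cbln1 (−3.62), Pmch (−3.50) and Agt (−3.44).

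**Figure D1:**
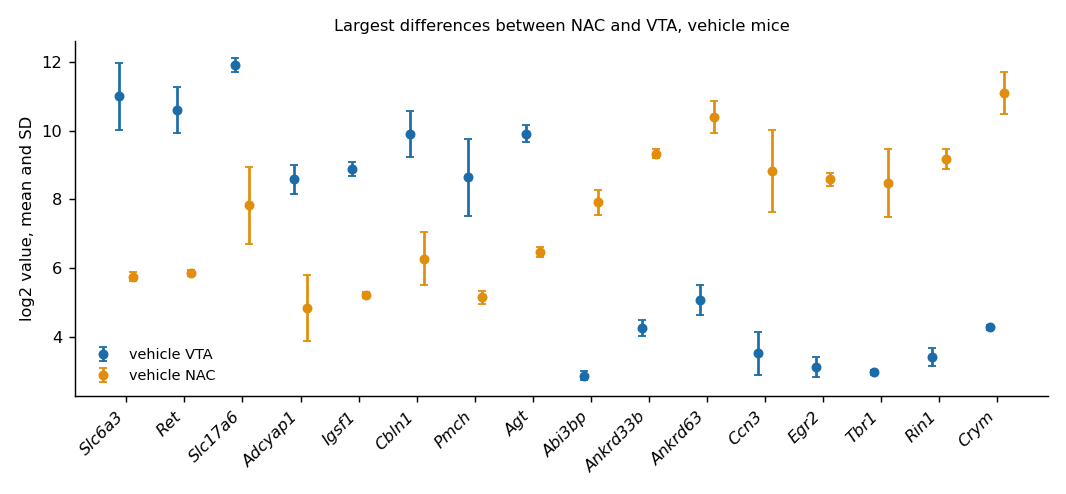
The plot shows log2 values (y axis) of the 8 genes with the largest difference in each direction between the NAC and VTA arrays of vehicle mice, among probe sets kept by the filter and past the test; points are group means and bars are SD over 5 arrays. Ret lies at 10.61 in VTA and 5.87 in NAC, and Crym at 4.28 in VTA and 11.1 in NAC.

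Other cell types differed between these 2 regions too. Oligodendrocyte markers were lower in NAC for 19 of 22 tested members (20 adjusted over the list alone), with Ermn at −1.43 (SE 0.19) and Olig1 at −1.19 (SE 0.081). Astrocyte markers were lower for 17 of 20 and higher for 1. Microglia markers were higher for 15 of 18, with Cd68 at 1.27 (SE 0.13). Endothelial and mural cell markers were lower for 9 of 17 members. Thalamic, hypothalamic and raphe neuron markers were lower for 6 of 13, with Tcf7l2, a thalamic transcription factor gene, at −3.05 (SE 0.26). Immediate early genes, which neuronal firing induces, were higher in NAC for 18 of 27 and lower for 2. Cortical excitatory neuron markers were higher in NAC for 14 of 24 members and lower for 1. Their spread among the 5 vehicle NAC arrays was wide, with an SD of 0.98 for Tbr1 and 1.61 for Neurod6. With limma, 15953 of 27022 probe sets passed adjusted p 0.05 (8178 higher and 7775 lower in NAC), of which 1223 were higher and 809 lower by more than 1. The PFC arrays were not set against the others at the level of single genes, because their values lay higher at the 1st percentile, the median and the 99th percentile (3.01, 7.24 and 12.3, against 2.65, 6.78 and 11.9 in VTA and 2.64, 6.85 and 11.9 in NAC).

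The comparison of modafinil with vehicle in VTA asked which transcripts differ in the dopamine cell region after the drug conditioning. Among the genes that rose were Rasgrp1, a Ras activator, by 1.91 (SE 0.34; 7.64 ± 0.78 against 5.73 ± 0.49, n = 5 each), Rgs16, a regulator of G protein signalling, by 1.68 (SE 0.23), and Prkcd, which encodes protein kinase C delta, by 1.67 (SE 0.29). Endou (1.40), Plekhg1 (1.38), Shisa6 (1.33), Ildr2 (1.32), Synpo2 (1.29), Rora (1.29) and Pdp1 (1.27) completed the 10 largest changes upward among genes past the test. The 10 largest changes downward among genes past the test were led by Vit (−0.79, SE 0.14), Prima1 (−0.77, SE 0.11), Pou3f1 (−0.67, SE 0.12), Cdc73 (−0.58) and Lbh (−0.58). The others were Mob3b (−0.54), Fam107b (−0.50), Rgs6 (−0.50), Cast (−0.50) and Ntrk3 (−0.47). For each of these 20 genes all 5 modafinil arrays lay on the same side of the vehicle mean. The genes were chosen by the test on these same arrays, so this is no separate evidence. Of 27022 probe sets, 70 passed with limma (51 higher and 19 lower, 59 named genes), with adjusted p-values from 0.0454 upward. An unadjusted p under 0.05 was found for 5695 (1849 higher and 3846 lower), where 1351 would by chance. The count rested on single arrays and on the settings. It was 0 without vehicle array 1, 2 or 3 or modafinil array 4, 2 without modafinil array 2 or 5, and 172 without modafinil array 3. It was also 0 with no filter on dim probe sets or with replicate blocks, 1 with 1 probe set per gene, 294 after quantile normalization (222 higher and 72 lower), and 241 to 1043 with the stricter filter, trend and robust estimation, arrayWeights or all 36 arrays in 1 fit. With the dopamine marker level of each array as a covariate it was 0, while the median size of the 70 changes went from 0.61 to 0.53 and their median SE from 0.10 to 0.14.

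Dopamine neuron markers had lower values in the modafinil VTA arrays for 19 of 19 tested members, none past the test over all probe sets and 17 adjusted over the list alone. Slc6a3 had a value of −1.84 (SE 0.54, adjusted p = 0.103) and Th, the rate-limiting enzyme of dopamine synthesis, −1.50 (SE 0.49, adjusted p = 0.131). The vesicular transporter gene Slc18a2 had a value of −1.55 (SE 0.51, adjusted p = 0.133) and Sncg −0.85 (SE 0.17, adjusted p = 0.0523). The mean level of the list differed by −0.91 (SE 0.32), with 4 of 5 modafinil arrays below the lowest vehicle array (exact permutation p = 0.0238, adjusted over 23 lists 0.137). Thalamic, hypothalamic and raphe markers moved the other way, with a mean level 0.38 higher (SE 0.14, exact permutation p = 0.0476, adjusted 0.156). Only 1 of 5 modafinil arrays lay above the highest vehicle array. Of 16 members 13 had higher values and 3 lower, and 3 were higher adjusted over the list alone. The 2 probe sets of Prkcd named here, which marks thalamic neurons, gave 1.67 and 2.16 (SE 0.43, adjusted p = 0.0523). GABA receptor genes of thalamic and cortical neurons had values of 1.69 for Gabrd (SE 0.34, adjusted p = 0.0523) and 1.22 for Gabra4 (SE 0.26, adjusted p = 0.0555). Oligodendrocyte markers had lower values for 21 of 22 members (0 past the test over all probe sets, 7 adjusted over the list alone), with a mean level of −0.18 (SE 0.069). In limma's camera test the dopamine and oligodendrocyte lists shifted down (adjusted p = 5.73e-07 and 0.000584) and the thalamic list up (4e-06). These became adjusted p = 0.349, 0.409 and 0.111 with an estimated correlation between genes.

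**Figure D2:**
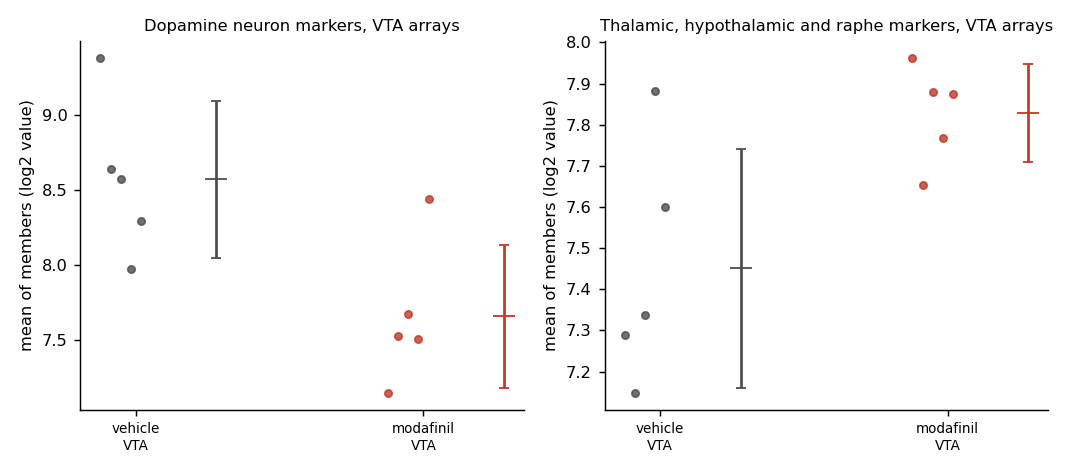
The plots show the mean log2 value (y axis) of the midbrain dopamine neuron markers and of the thalamic, hypothalamic and raphe neuron markers in each VTA array (points), with the group mean and SD (bars, n = 5 each). Dopamine markers lie lower in 4 of 5 modafinil arrays than in any vehicle array.

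The list of genes induced by interferon gamma, an immune cytokine, had higher values in the modafinil VTA arrays for 30 of 32 tested members. Of these, 1 passed over all probe sets and 18 adjusted over the list alone. The list also holds receptor and kinase genes of the pathway (Ifngr1, Ifngr2, Jak1 and Jak2) and genes that other interferons induce too, such as Stat2, Irf7 and Ifit1. It cannot tell which interferon lay behind a change. Stat2, a transcription factor of interferon signalling, rose by 0.47 (SE 0.075, adjusted p = 0.0454), and the immunity-related GTPase gene Igtp had a value of 1.92 (SE 0.39, adjusted p = 0.0523). Of 18 antigen presentation genes, 1 passed over all probe sets, and adjusted over the list alone 11 were higher and 1 lower. The immunoproteasome subunit gene Psmb9 rose by 1.01 (SE 0.18, adjusted p = 0.0497), and B2m, the light chain of class I molecules, had a value of 0.70 (SE 0.18, adjusted p = 0.0822). Of 19 circadian clock genes, Ciart rose by 0.61 (SE 0.10) and Hlf by 1.03 (SE 0.18), each with adjusted p = 0.0462, and 6 were higher adjusted over the list alone. The camera test gave adjusted p = 7.33e-21 for the interferon list, 9.81e-10 for the antigen presentation list and 9.81e-10 for the clock list; each was adjusted p = 0.111 with an estimated correlation. The series title names interferon gamma-regulated genes, so the interferon list is not independent evidence of its direction. The arrays with a raised interferon list were not all those with lower dopamine markers. Against the vehicle mean, modafinil array 5 stood at 0.82 on the interferon list and −0.13 on the dopamine list, and array 3 at −0.04 and −0.89.

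In NAC no gene passed the test between modafinil and vehicle. Among probe sets with 1 gene symbol the smallest p-values belonged, for higher values, to H2-D1, a class I antigen presentation gene (0.81, SE 0.18), Icam2 (0.48), Igtp (1.55, SE 0.35), Gm2115 (0.38), Srgn (0.45) and Pcolce (0.35). Among lower values they belonged to the imprinted gene Nnat (−0.51, SE 0.088), Btg1 (−0.43), Chd7 (−0.42), Dlx6os1 (−0.37), Brca1 (−0.45) and Tle4 (−0.46). Each of these 12 had all 5 modafinil arrays on that side of the vehicle mean and an adjusted p = 1. They were chosen by p on these same arrays, so the shared side is no separate evidence. With limma 0 of 27022 probe sets passed, and 874 had an unadjusted p under 0.05 where 1351 would by chance. Leaving out modafinil array 4 gave 1. Of 30 tested members of the interferon list 26 had higher values. Adjusted over the list alone 12 were higher, with Gbp3, a guanylate-binding protein gene, at 1.14 (SE 0.27). Of 16 antigen presentation genes, 4 were higher adjusted over the list alone, among them B2m at 0.80 (SE 0.20) and Psmb8 at 0.84 (SE 0.23). Of 19 clock genes, 3 were higher and 1 lower adjusted over the list alone, with Nr1d2 at 0.32 (SE 0.082), Per2 at 0.24 (SE 0.061) and Arntl, which encodes the activator BMAL1, at −0.40 (SE 0.12). The camera test gave adjusted p = 2.11e-22, 8.69e-10 and 2.71e-05 for these 3 lists, and adjusted p = 0.142, 0.141 and 0.142 with an estimated correlation.

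Cell type lists shifted in NAC as well. Striatal neuron markers had lower values for 20 of 22 members (camera adjusted p = 0.00186; adjusted p = 0.869 with an estimated correlation). Cortical neuron markers had higher values for 18 of 24 (0.00445; adjusted p = 0.862 with an estimated correlation), with no member of either past a test. Chrm4, a muscarinic receptor gene of striatal neurons, had a value of −0.28 (SE 0.10) and the cortical marker Lmo3 0.41 (SE 0.17). Oxidative phosphorylation genes had higher values for 72 of 85 members (adjusted p = 1.1e-12; adjusted p = 0.65 with an estimated correlation). Ribosomal protein genes shifted up as deposited (adjusted p = 0.000257; adjusted p = 0.869 with an estimated correlation). After quantile normalization that call was lost and the sign of the test changed (adjusted p = 0.637). Vehicle array 1 of NAC was dim among bright probe sets. Its 99th percentile was 11.43 where the next array of its group had 11.88. Its probe sets at 12 or above differed by a median of −0.76 from those of the other NAC arrays. On the oxidative phosphorylation list this array stood at 10.39, where the nearest array of its group had 10.63. The mean level of that list differed by 0.0986 between modafinil and vehicle NAC arrays (SE 0.0745, exact permutation p = 0.23, adjusted 0.756). The meningeal list (9 of 11 values higher, adjusted p = 4.71e-05) and the endothelial list (13 of 17, adjusted p = 0.00148; Slc2a1, the glucose transporter of brain vessels, at 0.47, SE 0.12) also shifted up, with adjusted p = 0.303 and 0.401 with an estimated correlation.

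In PFC the genes that rose with modafinil were led by interferon-induced genes. Gbp2 rose 5.76-fold (2.53 on the log2 scale, SE 0.445, 8.98 ± 1.42 against 6.45 ± 0.30, n = 8 each, adjusted p = 0.0396). Irgm2 rose by 1.60 (SE 0.27, adjusted p = 0.0327) and Gbp3 by 1.18 (SE 0.21, adjusted p = 0.0371), each in 7 of 8 modafinil arrays. In 8 of 8 arrays rose AW112010 (1.29, SE 0.20), the peptide transporter gene Tap1 (0.86, SE 0.14), Trim21 (0.48, SE 0.077), the transcription factor gene Irf7 (0.43, SE 0.071), Mthfd1l, a mitochondrial folate enzyme (0.43, SE 0.077), and Tapbp, which loads peptides onto class I molecules (0.35, SE 0.053). Wdfy3, an autophagy gene, fell by 0.40 (SE 0.064, adjusted p = 0.0297). Ifi47 (1.63, SE 0.30, adjusted p = 0.0539), Iigp1 (2.33, SE 0.44), Gbp7 (0.97), Igtp (1.46), Tnfsf10 (1.03) and Irgm1 (0.83) had the smallest p-values beyond these among higher values of probe sets with 1 gene symbol. Among lower values they were those of Arntl (−0.34, SE 0.061, adjusted p = 0.0508), Gm17733 (−0.29), Tmed7 (−0.24), Rbm45 (−0.34), Smc1a (−0.37) and Taok1 (−0.31). With limma 14 of 27022 probe sets passed (12 higher and 2 lower, 10 named genes), and 3181 had an unadjusted p under 0.05 (980 higher and 2201 lower).

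Of the 32 members of the interferon list tested in PFC, 5 were higher over all probe sets, and adjusted over the list alone 24 were higher and 2 lower. The lower 2 were the receptor gene Ifngr2 at −0.27 (SE 0.083) and the kinase gene Jak1 at −0.16 (SE 0.068). Antigen presentation genes were higher for 1 of 18 over all probe sets, and 12 were higher and 1 lower adjusted over the list alone. The camera test gave adjusted p = 6.82e-33 and 2.08e-14, and both lists held with adjusted p = 0.0352 with an estimated correlation. Clock genes had 0 of 19 past the test over all probe sets and 7 higher and 3 lower adjusted over the list alone, with Dbp at 0.53 (SE 0.12), Per2 at 0.36 (SE 0.081) and Nfil3 at −0.52 (SE 0.15). The list's adjusted p = 0.00514 became adjusted p = 0.51 with an estimated correlation. Oligodendrocyte markers had higher values for 21 of 22 members (0 past either test; adjusted p = 2.33e-08, and adjusted p = 0.51 with an estimated correlation), with Cldn11 at 0.44 (SE 0.14). Vehicle PFC array 3 stood apart on this list, at 8.68 where the next lowest vehicle array had 8.97. Striatal markers had higher values for 15 of 17 (adjusted p = 0.000361, and adjusted p = 0.51 with an estimated correlation). Modafinil PFC array 3 stood at 9.50 on that list where the next array of its group had 8.385. The count of 14 was 0 without any of vehicle arrays 1, 3, 6, 7 and 8 or modafinil arrays 1, 2, 4, 5, 7 and 8. It was 8 without vehicle array 5, 52 without modafinil array 3 and 62 without modafinil array 6. It was 0 with eBayes using a trend and robust estimation or with replicate blocks, 4 with the stricter filter, and 36 to 61 with all 36 arrays in 1 fit, arrayWeights or the doubted arrays left out.

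Fitted over all 36 arrays with the region as a factor, the comparison asked for a change shared by the 3 regions. Among genes past the test, most of the largest changes upward were again those of genes on the interferon list. Gbp2 rose by 2.42 (SE 0.33, adjusted p = 4.34e-05), with 16 of 18 modafinil arrays above the vehicle mean of their region. Then came Iigp1 by 2.31 (SE 0.32, 15 of 18), Ifi47 by 1.64 (SE 0.225, 18 of 18), Gbp6 by 1.63, Igtp by 1.61 (SE 0.21, adjusted p = 4.2e-05), Irgm2 by 1.61, Gbp7 by 1.32, Xdh by 1.19, Gbp3 by 1.18 and AW112010 by 1.17. Of these, Xdh and AW112010 are not on that list. Of 32 tested members of the interferon list 24 rose over all probe sets and 26 adjusted over the list alone, with none lower. Irf1, which switches on many interferon targets, rose by 0.41 (SE 0.083, adjusted p = 0.00692). Of 18 antigen presentation genes 11 rose over all probe sets, and 12 were higher and 1 lower adjusted over the list alone, among them B2m (0.69, SE 0.12), Psmb8 (0.92, SE 0.14) and Psmb9 (0.74, SE 0.11). The receptor gene Ifngr1 had a value of −0.01 (SE 0.029, adjusted p = 0.922). The gene of the cytokine itself, Ifng, lay near the floor of the arrays with group means between 2.71 and 3.11. The camera test gave adjusted p = 8.12e-51 and 4e-22, and both lists held with adjusted p = 0.00085 with an estimated correlation.

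**Figure D3:**
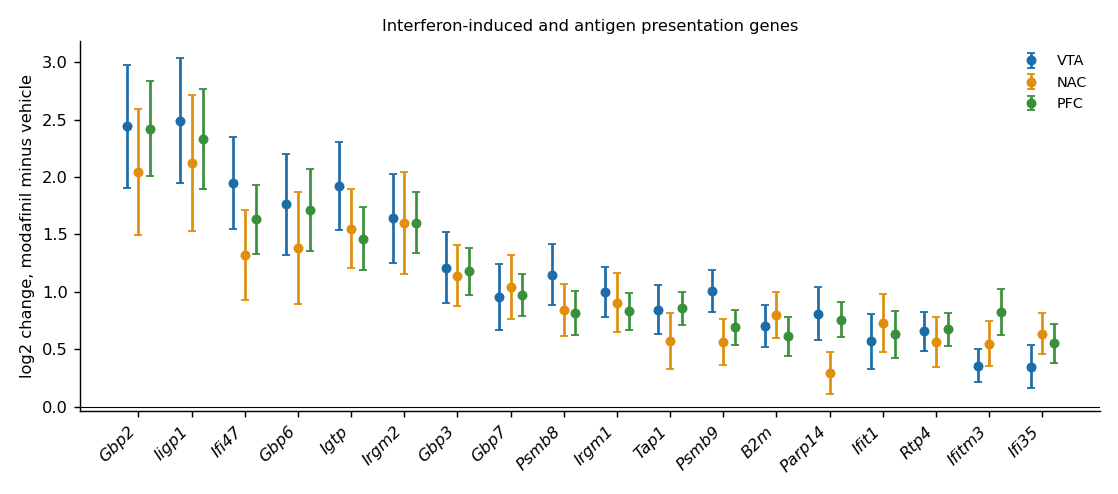
The plot shows the log2 change between modafinil and vehicle (y axis, points, bars ± SE) in VTA (5 against 5 arrays), NAC (5 against 5) and PFC (8 against 8) for the 18 interferon-induced and antigen presentation genes with the largest upward change among list members past the test across the regions, 1 probe set per gene. All 18 lie above 0 in the 3 regions, with Gbp2 at 2.44 in VTA, and Ifi35 at 0.35 there.

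The interferon list was not raised in every modafinil array. Its mean level rose from 7.36 ± 0.088 to 7.97 ± 0.38 in PFC (mean ± SD, n = 8 each, difference 0.62, SE 0.14, exact permutation p = 0.00186, adjusted over 23 lists 0.0251), and 7 of 8 modafinil arrays lay above the highest vehicle array. In VTA it stood at 7.68 ± 0.40 against 7.02 ± 0.098 (difference 0.67, SE 0.19, exact permutation p = 0.0317, adjusted 0.146). In NAC it stood at 7.34 ± 0.44 against 6.79 ± 0.066 (difference 0.55, SE 0.20, exact permutation p = 0.0397, adjusted 0.304), each with 4 of 5 modafinil arrays above the highest vehicle array. The smallest p these exact tests can give is 0.00794 with 5 against 5 arrays and 0.000155 with 8 against 8. Against the vehicle mean of their region, modafinil VTA array 3 stood at −0.04, NAC array 4 at −0.053, PFC array 6 at −0.063, PFC array 3 at 0.15 and NAC array 3 at 0.21. The other modafinil arrays stood at 0.62 to 1.00. Microglia markers differed by 0.046 (SE 0.049) in VTA, 0.017 (SE 0.077) in NAC and 0.052 (SE 0.060) in PFC, with exact permutation p-values of 0.405, 0.849 and 0.398.

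**Figure D4:**
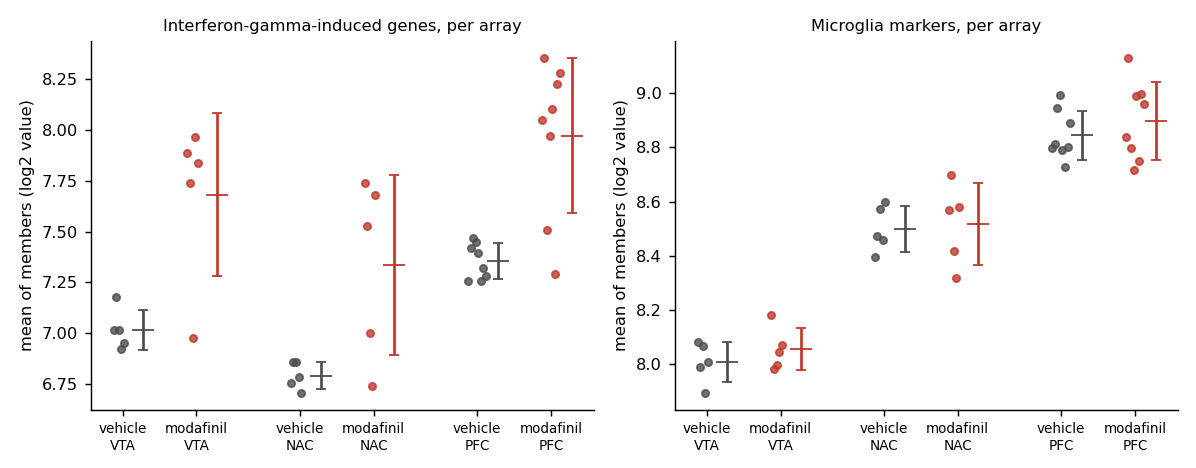
The plots show the mean log2 value (y axis) of the interferon gamma-induced genes and of the microglia markers in each array (points), with mean and SD per group (bars, n = 5 in VTA and NAC groups and 8 in PFC groups). In each region at least 1 modafinil array lies at the vehicle level of the interferon list while most lie above it, and the microglia levels of the treatment groups overlap.

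Clock genes formed the next group across the regions. Per2, a repressor in the clock loop, rose by 0.30 (SE 0.046, adjusted p = 0.000129) in 18 of 18 modafinil arrays. Ciart rose by 0.49 (SE 0.083, adjusted p = 0.000679), Dbp by 0.47 (SE 0.092, adjusted p = 0.00429), Nr1d2 by 0.20 (SE 0.036, adjusted p = 0.00197) and Per3 by 0.15 (SE 0.036, adjusted p = 0.0302). Arntl fell by 0.25 (SE 0.059, adjusted p = 0.0286) in 16 of 18. That made 5 of 19 higher and 1 lower over all probe sets, and 10 higher and 3 lower adjusted over the list alone. The list held with adjusted p = 0.00666 with an estimated correlation (5.76e-11 with the preset one). The regions were not alike: Arntl had a value of 0.03 in VTA, −0.40 in NAC and −0.34 in PFC, and Hlf 1.03, 0.22 and 0.05. Of 20 glucocorticoid-responsive genes Tsc22d3 rose by 0.21 (SE 0.047, adjusted p = 0.0151), and 5 were higher and 2 lower adjusted over the list alone. Zbtb16 stood at 0.40 (SE 0.11, adjusted p = 0.0697) and the cell cycle inhibitor gene Cdkn1a at −0.22 (SE 0.058, adjusted p = 0.0591). The astrocyte transcription factor gene Sox9 fell by 0.25 (SE 0.050, adjusted p = 0.00486, 17 of 18 arrays).

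**Figure D5:**
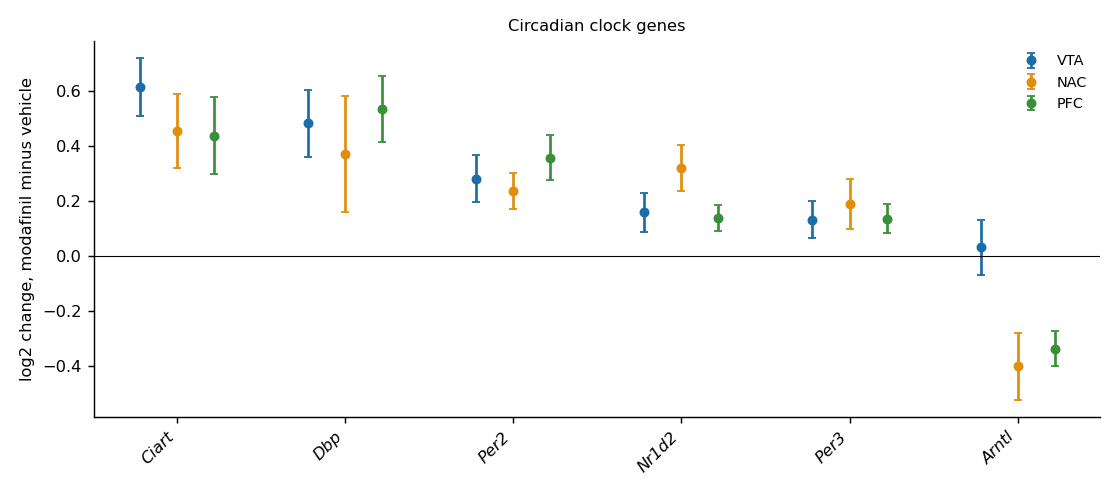
The plot shows the log2 change between modafinil and vehicle (y axis, points, bars ± SE) in VTA (5 against 5 arrays), NAC (5 against 5) and PFC (8 against 8) for the 6 clock genes past adjusted p 0.05 across the regions. Per2 lies between 0.24 and 0.36 in the 3 regions, and Arntl at 0.03 in VTA, −0.40 in NAC and −0.34 in PFC.

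Among genes past the test, the 10 largest changes downward across the regions were those of Erdr1 (−0.66, SE 0.17, adjusted p = 0.0437), Gucy1a1, a subunit of the nitric oxide receptor (−0.41, SE 0.096, adjusted p = 0.0279), Isoc1 (−0.36), Dcdc2a (−0.35, 18 of 18 arrays), Gm266 (−0.34), Rps6ka6 (−0.31), the chemokine gene Cxcl12 (−0.30, SE 0.067, adjusted p = 0.0155), Zfp783 (−0.28), BC030500 (−0.28) and the membrane protease gene Mmp14 (−0.28, SE 0.058, adjusted p = 0.00721). With limma 227 of 27022 probe sets passed (120 higher and 107 lower, 177 named genes), and 4479 had an unadjusted p under 0.05 (976 higher and 3503 lower). After quantile normalization of all arrays together the split was 135 higher and 34 lower of 169. The arrays of the 3 regions may come from the same mice, in which case these p-values are too small; with arrays of the same treatment and number as a random block, 118 passed (90 higher and 28 lower), and of the 10 downward genes above only Cxcl12 and Mmp14 did. With the stricter filter 140 passed, with replicate blocks 122 and with arrayWeights 556. Leaving out 1 array gave 145 without modafinil VTA array 1, 147 without modafinil NAC array 1, 348 without vehicle NAC array 2 and 389 without modafinil NAC array 3.

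Receptor, transporter and signalling lists showed small shifts. Immediate early genes had no member past the test over all probe sets in any region. Fos had values of −0.14, 0.28 and −0.003 in VTA, NAC and PFC, and Arc −0.19, 0.06 and 0.10. Adjusted over the list alone the only calls were in PFC, Egr4 at 0.21 (SE 0.056) and Bdnf, a growth factor gene, at −0.33 (SE 0.099). Their camera adjusted p-values were 0.053, 0.774 and 0.0689, and across the regions the list was called (0.0167; adjusted p = 0.444 with an estimated correlation). In VTA the camera test called the glutamate receptor list (adjusted p = 0.0133), the GABA list (0.0201), the neuropeptide list (0.0316) and the cortical marker list (0.0325), each up, with no member past the test over all probe sets and 0, 3, 3 and 2 higher adjusted over the list alone. Npy had a value of 0.62 (SE 0.14, adjusted p = 0.0604) and Hcrt, the orexin precursor gene, 0.90 (SE 0.25, adjusted p = 0.0892). Hcrt is also on the thalamic, hypothalamic and raphe list, which lay higher in these arrays, so another mix of tissue could give its value. The camera values of the lists called in VTA became adjusted p = 0.265, 0.297, 0.297 and 0.297 with an estimated correlation between genes. The GABA list's median was −0.002 where its mean was 0.15. The monoamine, orexin and histamine receptor list was not called in any region (adjusted p = 0.226, 0.774 and 0.322), with the orexin receptor gene Hcrtr1 at −0.60 (SE 0.15, adjusted p = 0.0753) in VTA. Across the regions it was called (0.0268), with a median of −0.012 and a mean of 0.009, and was adjusted p = 0.0863 with an estimated correlation. The preset test called 12 lists in VTA, 9 in NAC and 10 in PFC, 31 of 69. With an estimated correlation 3 held, all in PFC, the interferon, antigen presentation and choroid plexus lists. Across the regions it called 15 of 23, 14 up and the dopamine marker list down, and with an estimated correlation the interferon, antigen presentation and clock lists held.

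The remaining lists had few or no members past a test. Heat shock genes had lower values in VTA for 19 of 23 members (0 past the test over all probe sets, 4 adjusted over the list alone, camera adjusted p = 0.151), with the chaperone partner gene Bag3 at −0.37 (adjusted p = 0.0607). In NAC and PFC their camera adjusted p-values were 0.774 and 0.883. Glucocorticoid-responsive genes shifted up in VTA (adjusted p = 0.00183; adjusted p = 0.297 with an estimated correlation) and PFC (0.0361; adjusted p = 0.51 with an estimated correlation), with Klf9, a steroid-responsive transcription factor gene, at 0.31 in VTA (adjusted p = 0.0633). Microglia markers shifted up by small amounts in VTA (median 0.058, adjusted p = 0.00801; adjusted p = 0.433 with an estimated correlation) and PFC (median 0.051, adjusted p = 0.0036; adjusted p = 0.617 with an estimated correlation), with no member past either test. Endothelial and ribosomal protein lists shifted up in PFC (adjusted p = 0.0128 and 1.05e-06; adjusted p = 0.668 and 0.567 with an estimated correlation). The choroid plexus list, of which 4 members were tested in PFC, had a median of 0.088 there (adjusted p = 0.00347), with 1 member higher adjusted over the list alone. The camera test did not call astrocyte markers (adjusted p = 0.897, 0.112 and 0.626 in VTA, NAC and PFC). Nor did it call red blood cell genes (0.735, 0.774 and 0.742) or, outside NAC, meningeal markers (0.321 in VTA and 0.813 in PFC). The mean level of the astrocyte list in VTA differed by −0.106 (SE 0.0445, exact permutation p = 0.0238, adjusted 0.137). There 4 of 5 modafinil arrays lay below the lowest vehicle array, and 3 of 20 members were lower adjusted over the list alone. Without the doubted arrays the meningeal list in PFC turned direction (adjusted p = 0.000736), but 2 of those arrays were doubted for these same markers, so that value is no evidence of a change. Oxidative phosphorylation genes had adjusted p = 0.0906 in VTA and 0.883 in PFC.

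Whether the modafinil change differed between regions was tested as an interaction over the 6 groups. Between NAC and VTA, Npas2, a clock transcription factor gene, differed by −0.87 (SE 0.12, adjusted p = 0.000253, with 0.57 in VTA and −0.30 in NAC). The probe set of Npas2 used for the clock list had 0.41 (SE 0.26) in VTA and −0.21 (SE 0.13) in NAC. Of 19 clock genes on that list 0 passed in this contrast. Synpo2 differed by −1.37 (1.29 in VTA and −0.08 in NAC), Plekhg1 by −1.46, Gjc1 by −0.79 and Prkcd by −1.72 (1.67 and −0.05). Between PFC and VTA, Synpo2 differed by −1.28 (SE 0.17, adjusted p = 0.000213; 0.01 in PFC), Plekhg1 by −1.38, Rora by −1.49, Gjc1 by −0.75 and Prkcd by −1.62. Among list members, 3 of 11 dopamine markers were higher and 3 of 13 thalamic markers lower in PFC minus VTA. Also lower there were 2 of 19 clock genes, 2 of 18 GABA genes, 2 of 24 cortical markers, 1 of 20 neuropeptide genes and 1 of 84 oxidative phosphorylation genes. In NAC minus VTA 2 of 18 GABA genes and 1 of 13 thalamic markers were lower. Prkcd and Rora, named above, are on the thalamic, hypothalamic and raphe list. Another placement of the VTA punches, which stays open, could also give such differences. The interactions cannot tell it from a drug effect that differs between regions. No member of 32 on the interferon list and no antigen presentation gene of 18 passed in any of the 3 contrasts. Within the regions, PFC had calls over all probe sets for 5 members of the interferon list where NAC had 0. In the simulation these contrasts found a change of 0.5 in 53.5, 53.1 and 58.2 percent of changed probe sets. Differences of that size can thus be missed. With limma 74 probe sets passed for NAC minus VTA (8 higher and 66 lower), 244 for PFC minus VTA (45 and 199) and 0 for PFC minus NAC. In the last, 1328 had an unadjusted p under 0.05, and the smallest adjusted p was 0.838. Among probe sets with 1 gene symbol, Eral1, Arntl2, Fkbp5, Zfp52 and Stard5 had the smallest p-values (adjusted p = 0.914). On simulated data 21.6, 11.9 and 24 percent of all calls of these 3 contrasts were unchanged probe sets. The regions may share mice, which these p-values leave out. Leaving out 1 array gave 46 to 177 for NAC minus VTA and 116 to 310 for PFC minus VTA, and quantile normalization gave 168 for NAC minus VTA.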

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

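The explanations weighed here for the interferon and clock patterns were, except for normalization, tested with tests chosen after the result was seen, as were plain dilution of the dopamine cells and the dopamine level as a covariate. Within groups, 252 sets of values were tested for a lone array and 24 stood apart, where chance alone flags about 1 group in 20. The value given for each is the gap to the nearest array as a share of the range of the group.

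In modafinil VTA array 3 the interferon list was lowest (0.771, level 6.98 where the nearest array had 7.74), and with it Gbp2 (0.921), Igtp (0.778), Irgm2 (0.891), B2m (0.844) and Irf1 (0.785). Modafinil VTA array 1 was lowest on the monoamine receptor list (0.752) and at its 99th percentile (0.875). Vehicle VTA array 4 was highest on choroid plexus markers (0.923, 6.89 where the nearest had 5.58), and vehicle VTA array 2 lowest on ribosomal protein genes (0.76). Vehicle NAC array 1 was lowest on oxidative phosphorylation genes (0.711) and at its 99th percentile (0.894), and vehicle NAC array 2 was highest for Arc (0.877). Vehicle PFC array 2 was lowest on heat shock genes (0.553), vehicle PFC array 3 on oligodendrocyte markers (0.538) and modafinil PFC array 1 on immediate early genes (0.577). Vehicle PFC array 4 was highest for Slc6a3 (0.633) and Slc18a2 (0.555). Modafinil PFC array 3 was highest on striatal markers (0.841), dopamine markers (0.563), neuropeptides (0.691), Drd1 (0.59), Drd2 (0.764) and Ppp1r1b (0.778). The interactions of modafinil with region called 74 probe sets for NAC minus VTA and 244 for PFC minus VTA.

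The interferon list lay at the vehicle level in some modafinil arrays and clearly above it in others. Labels swapped between groups were argued against, because 0 of 18 vehicle arrays lay above the midpoint of their region's group means, although a single wrong label stays open. More microglia, vessel, meningeal or red blood cell tissue in the modafinil punches was argued against by the largest difference of those lists, 0.142 (SE 0.0935, meningeal, NAC). The smallest difference of the interferon list was 0.546. No list held markers of other immune cells, so a larger share of those was not tested. Quantile normalization of the deposited values left 0.572 in NAC, 105 percent of the deposited difference, with 102 percent in VTA and 101 in PFC. The deposited values were already RMA output, so this argues only against scale differences left between arrays. It cannot test the original normalization. Why some modafinil arrays stayed at the vehicle level was left open.

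Dopamine markers were lower and thalamic markers higher in the modafinil VTA arrays. Another placement of the punches fits: 82.9 percent of the 70 called probe sets went the way that the dopamine level predicts within groups, where 64.1 percent of those at p under 0.05 and 56 percent of all did. With the dopamine level as a covariate the median size of the 70 changes went from 0.607 to 0.531 and its SE from 0.104 to 0.143, and 0 passed, while the interferon list in VTA went from 0.511 to 0.483. The changes kept most of their size and the SE grew, so the lost calls do not speak for tissue. A lower share of dopamine neurons with every other cell type raised alike was argued against, because the oligodendrocyte level differed by −0.177, and both the placement of the punches and a drug effect on dopamine cells stay open.

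Clock genes shifted across the regions, though not alike in each. With 4 marker levels as covariates a median of 92.7 percent of the change was left over the 13 genes past the test adjusted over the list alone, and 9 of 13 still passed, among them all 6 called over all probe sets (Per2 from 0.303 to 0.299, Ciart 0.491 to 0.45, Dbp 0.475 to 0.435, Arntl −0.251 to −0.316). Hlf went from 0.371 (SE 0.104) to 0.169 (SE 0.0777) and Rora, itself a thalamic list member, from 0.412 (SE 0.14) to 0.183 (SE 0.113). Usp2 went from 0.163 (SE 0.0573) to 0.0892 (SE 0.0569). With these falls another mix of tissue was not excluded for the list as a whole. Per1 also lost its call but kept most of its size, from 0.153 (SE 0.0495) to 0.119 (SE 0.0541). This test replaced narrower ones on fewer genes after their results were seen. A time of death that differed between the groups could give the same pattern and was not excluded, since 2 regions had Arntl lower and Dbp higher, and hours of death were not used here.

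Redrawn group labels gave at most 4 calls in VTA (70 with the real labels), 0 in PFC (14), 6 across the regions (227), 13 for PFC minus VTA (244) and 6158 between regions (15953). For NAC minus VTA they gave up to 515 (74), and chance was not excluded, with 5 of 100 draws as large. A draw several times the real count points to a structure of the samples, which no test located. In NAC and for PFC minus NAC the real count was 0, so all 100 draws were as large by construction, and the highest draws were 832 and 1318. Of lists, 31 were called with the real labels and up to 32 with redrawn ones (median 21), 4 of 100 draws being as large. Chance was thus a poor account of the gene counts in VTA and PFC. For the fit across the regions and for the interactions the labels were redrawn apart in each region. If the regions share mice, those draws leave out that link, so they cannot decide on chance there. The list counts with the preset correlation carry little weight by number alone.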

How the results depend on the processing

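The removal of doubted arrays and the dopamine covariate were chosen after the result was seen. In VTA the 70 calls became 1216 at a threshold of 0.1, 0 with no filter, 291 with the stricter filter, 294 after quantile normalization, 241 with trend and robust estimation, 704 with arrayWeights, 1 with 1 probe set per gene, 0 with replicate blocks, 1043 from all 36 arrays in 1 fit and 0 with the dopamine level as a covariate. Leaving out 1 array gave 0 to 172, with 0 without vehicle array 1, 2 or 3 or modafinil array 4, 2 without modafinil array 2 or 5 and 172 without modafinil array 3. In NAC it gave 0 to 1, the 1 without modafinil array 4, and other settings gave 0. In PFC the 14 calls became 52 at 0.1, 4 with the stricter filter, 0 with trend and robust estimation, 61 with arrayWeights, 0 with replicate blocks, 36 from all 36 arrays and 38 without doubted arrays. Leaving out 1 array gave 0 to 62, with 0 without vehicle array 1, 3, 6, 7 or 8 or modafinil array 1, 2, 4, 5, 7 or 8, 8 without vehicle array 5, 52 without modafinil array 3 and 62 without modafinil array 6. Across the regions the 227 calls became 606 at 0.1, 140 with the stricter filter, 556 with arrayWeights, 122 with replicate blocks and 118 with animals as a random block, and 145 to 389 with 1 array left out (145 without modafinil VTA array 1, 147 without modafinil NAC array 1, 348 without vehicle NAC array 2, 389 without modafinil NAC array 3). Whether equal numbers mark the same mouse stayed open. Between regions, 9 of 30 pairs of arrays with equal treatment and number correlated above 0.1. In 10 of 30 the best match was the array of the same number. That held in 4 of 5 for vehicle VTA with vehicle NAC and in 0 of 5 for vehicle NAC with vehicle PFC. Between treatments, where a mouse cannot be shared, 5 of 18 pairs correlated above 0.1 and 4 of 18 matched best. The 31 list calls became 3 with an estimated correlation and 28 to 34 with 1 array left out. The ribosomal list in NAC lost its call after quantile normalization, with the sign of the test changed (adjusted p = 0.637), and the meningeal list in PFC turned direction without doubted arrays (adjusted p = 0.000736). For NAC minus VTA the 74 calls became 186 at 0.1, 168 after quantile normalization, 534 with arrayWeights, 161 with animals as a random block and 116 without doubted arrays. Leaving out 1 array gave 46 to 177 (46 without vehicle VTA array 2, 48 without modafinil VTA array 1, 49 without vehicle NAC array 5, 116 without vehicle VTA array 5, 122 without modafinil VTA array 2, 177 without vehicle NAC array 2). For PFC minus VTA the 244 calls became 451 at 0.1 and 584 with arrayWeights, and 116 to 310 with 1 array left out (116 without modafinil VTA array 1, 154 without vehicle VTA array 2). For PFC minus NAC the 0 calls became 6 with arrayWeights and stayed 0 with 1 array left out. Between regions the 15953 calls became 2032 with a difference over 1, 25572 with no filter, 7545 with 1 probe set per gene and 14940 to 16444 with 1 array left out. Apart from the looser threshold and the size limit, whose direction follows from their construction, the cause was not tested. Of 12756 values of named genes 11841 kept both their sign and whether they were called, 577 lost a call and 152 gained one. The kept values include those with no call in either fit, so their share does not measure how stable the calls were. In 186 the sign changed with no call in either fit, and in 0 it changed with a call.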

Other observations

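No test in this part was chosen after the result was seen, apart from the weighing of patterns named elsewhere. Pmch, the melanin-concentrating hormone gene, stood at 8.65 ± 1.12 in vehicle VTA arrays and 5.15 ± 0.20 in NAC arrays (mean ± SD, n = 5 each). Tbr1, a cortical transcription factor gene, stood at 8.48 ± 0.98 in the vehicle NAC arrays and 2.98 ± 0.079 in VTA arrays, with the wider spread in NAC. The source of neither signal was tested.

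The signal over background limits what the arrays can say of weakly expressed transcripts. Ifng lay at group means of 2.71 to 3.11, near the lowest values of the arrays (1st percentile 2.65 in VTA and 3.01 in PFC), so its absence of change carries no information on the cytokine. Punches mix many cell types, and a changed level can come from changed cells or changed cell numbers.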
